A study of Mus musculus with 8 samples.

How the data were processed

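Bulk RNA-seq was made from macrophages grown from C57BL/6 mouse bone marrow, with 4 vehicle and 4 SLIT2 libraries (6 nM, 16 hours). Per the labels' protocols, each library was made from 300 ng of total RNA with a stranded mRNA kit and sequenced as paired-end reads of 101 bp on a HiSeq 2500. Per the submitters' processing notes, the authors used FastQC 0.11.9, SAMtools 1.7, Picard 2.23.8, STAR, Salmon and DESeq2 with the builds mm10 and GRCm38. The role, order and settings of these tools are not given in the sources used here, nor is the strand setting of the counting.

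The deposited values are regularized-log values on a log2 scale, given by the authors to 2 decimals for 41444 genes and 8 libraries. The rlog transform corrects for library size and shrinks each value towards the gene's mean, most strongly at low counts, so differences of low genes are understated. Whether it was run blind to the groups is not given in the sources used here. Of the genes, 20992 held a single value in every library and 20347 of these were listed at 0. The table holds no read counts, so the depth per sample and its counting error are unknown. The order of genes in the table followed the unblocked p computed here (Spearman rho 0.988 across the 11851 genes tested, which are not independent replicates) more closely than the blocked p (rho 0.909).

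Genes with a mean rlog of at least 4 over the 8 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), SLIT2 against vehicle, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The main model had treatment only. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 29 of 33 lists with at least 5 genes tested, and beside it with an estimated correlation and with fry. Alternatives were a replicate block, other filters, variance priors, scalings and sample weights, a minimum size of change, and leaving out each library. Coordinates, overlaps, GC content and transcript lengths came from GENCODE M21 on GRCm38, to which 41157 gene identifiers matched. Figures were drawn with matplotlib 3.10.9.

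Groups, main tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 genes per direction with the widest difference among those past the threshold with non-overlapping groups, leaving out clone and model names. It also took up to 3 called members of each list, or the member with the smallest p where none was called, and Slit2, Robo1, Robo2, Robo3, Robo4, Csf1r, Adgre1, Mrc1, Arg1, Tnf, Il1b and Vegfa. Stat3, Pim1, Bcl3, Nfil3, Yam1, Xist, Ddx3y, Ifit1, Tyrobp and Sbno2 were named after their values were seen. The results of 1 list tested, with the members named from it, and of 1 further gene are not reported here; every test kept them.

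Some steps were changed after the table was seen. List members were first matched by the table's own symbols, several of which are older names. They were then matched by gene identifier to the current symbol first, which altered the tested members of 3 lists and changed the call of 0 lists. The block on the replicate set, the fits within each set, the fit on averaged duplicates and the tests of the difference between the sets were also added then. A bound of 0.25 on the median of the STAT3 targets was written before their values were looked at, after 0.5 had been considered.

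The labels number the replicates 1 to 4 in both groups without saying what a number marks. Same-numbered samples deviated together from their group means (correlations across genes of 0.637, 0.671, 0.753 and 0.587), so the numbers were taken to pair the samples. What they share is the replicate set, since the difference of replicate 1 minus 2 correlated at -0.042 between the groups and that of 3 minus 4 at 0.088. The median SD was 0.061 within duplicates and 0.13 between the sets. Nothing in the labels says that the 4 replicates came from separate cultures or animals, so the p-values measure the spread between these samples, which may be technical. If each set is a single source, there are 2 sources per group. The tests within 1 set and of differences between sets then measure only the spread within duplicates.

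The steps were tested on simulated data with the means, set shifts and residual SD of the 11851 genes, with 50 genes changed at each of 4 sizes. For SLIT2 against vehicle without a block, 16% of genes changed by 0.25 on the log2 scale were recovered, 48% at 0.5, 86% at 1 and 96% at 2, and 1.6% of calls were false. With the replicate block, 56%, 76%, 94% and 100% were recovered and 2.98% of calls were false. For the difference between the sets, 12%, 42%, 78% and 96% were recovered and 1.72% of calls were false. A list raised by 0.5 was called by camera with the preset and the estimated correlation, and 0 other lists were. Noise was drawn independently for each gene and library from the residual SD within duplicates. The simulation held no correlation between genes and, for SLIT2 against vehicle, no difference in effect between the sets. Its shares of false calls and its list calls hold for that setting and may differ in the real data.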

Results

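The data were RNA-seq profiles of wild-type C57BL/6 mouse macrophages, grown from bone marrow in medium with the macrophage growth factor M-CSF. Cells received either vehicle or 6 nM SLIT2, a secreted ligand of the ROBO receptors best known from axon guidance, for 16 hours. The comparison asks how SLIT2 changes transcription in these cells. Each group held 4 samples, and values were regularized-log (rlog) expression values on a log2 scale. No read counts were given in the sources used here, so the depth per sample is unknown and no counting interval can be attached to any value. Of 41444 genes listed, 11851 had a mean rlog of at least 4 and were tested.

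The libraries separated both by treatment and by replicate number. Replicates 1 and 2 lay apart from replicates 3 and 4 in the vehicle and in the SLIT2 group. This division took 46.7% of the sum of squares over the genes tested, treatment took 37.3%, their interaction 5.29% and the spread within duplicates 10.7%. Xist, the RNA that silences an X chromosome in female cells, averaged 7.54 ± 0.077 (SD, n = 4) in replicates 1 and 2 and 12.7 ± 0.044 (SD, n = 4) in replicates 3 and 4. Ddx3y, a Y-linked gene, averaged 10.8 ± 0.039 (SD, n = 4) and 6.23 ± 0.23 (SD, n = 4) in the same sets. Both genes were chosen after their values were seen. The sets are called replicate sets here, and values within each set are given for some results only.

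**Figure D1:**
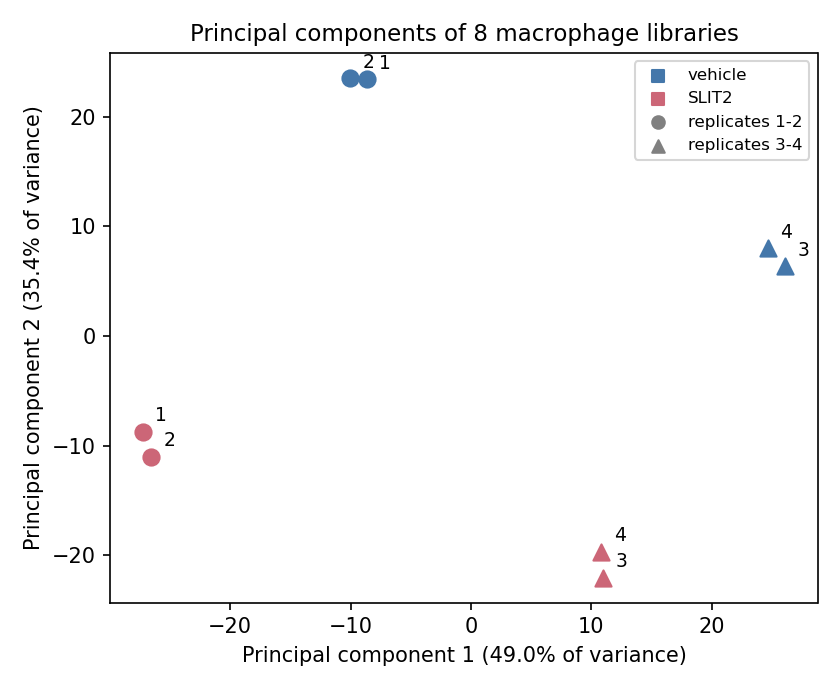
Scores of the 8 libraries on principal component 1 (horizontal axis, 49.0% of variance) and principal component 2 (vertical axis, 35.4% of variance), with vehicle in blue, SLIT2 in red, replicates 1 and 2 as circles and replicates 3 and 4 as triangles. The 4 duplicates lie close together, and the replicate sets stand apart within both treatments.

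The 10 genes that rose most with SLIT2 by the naming rule began with Socs3 and Saa3. Socs3, a feedback inhibitor of cytokine receptors (ENSMUSG00000053113, chromosome 11, 117966079 to 117970047 in GRCm38), rose from 7.84 ± 0.091 to 12.36 ± 0.14 (SD, n = 4), a log2 difference of 4.52 (SE 0.081, adjusted p = 7.64e-08). Il4ra, the alpha chain of the interleukin-4 receptor (ENSMUSG00000030748, chromosome 7, 125552120 to 125579474), rose by 3.31 (SE 0.20, adjusted p = 6.13e-05). The acute-phase gene Saa3 rose by 3.91 (SE 0.67, adjusted p = 0.00678) and Il1b, which encodes the cytokine interleukin-1 beta, by 2.75 (SE 0.41, adjusted p = 0.00354). In replicates 1 and 2 and in replicates 3 and 4, Socs3 rose by 4.57 and 4.47, Il4ra by 3.35 and 3.28, Saa3 by 4.27 and 3.55 and Il1b by 2.97 and 2.53. The chemokine genes Ccl8 and Ccl12 rose by 3.62 and 3.25, the gap junction gene Gja1 by 3.54, the adenosine receptor gene Adora3 by 3.12, the metalloreductase gene Steap4 by 3.07 and the complement gene C4b by 2.90. In the same sets Adora3 rose by 3.05 and 3.19 and C4b by 3.13 and 2.66. Of these 10 genes, 4 passed a limma test of the difference between the sets, which rests on the spread within duplicates. They were Ccl8 (4.52 and 2.71, adjusted p = 0.00209), Steap4 (4.10 and 2.04, 0.00704), Ccl12 (3.68 and 2.81, 0.0431) and Gja1 (3.77 and 3.32, 0.0473). Reads of Adora3 cannot be separated here from the overlapping gene Tmigd3, which shares 779 exonic bases on the same strand. The strand setting of the authors' counting is not given in the sources used here, and an antisense gene shares 571 exonic bases with Il4ra.

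The 10 genes that fell most by the same rule included Kif23 and Dcstamp. Kif23, a mitotic kinesin (ENSMUSG00000032254, chromosome 9, 61915905 to 61946774), fell by 1.38 (SE 0.094, adjusted p = 9.18e-05). Dcstamp, needed for fusion of osteoclast precursors, fell by 1.40 (SE 0.24, adjusted p = 0.00615). Cgnl1, a junction protein gene, fell by 1.5 and Rgs1, a regulator of G protein signalling, by 1.38. Serpinb6b fell by 1.63, Efr3b by 1.73, Tox2 by 1.55, Rasgrp3 by 1.44 and Cmah by 1.44. Rsc1a1 fell by 2.08 (SE 0.31, adjusted p = 0.00360), from 6.66 ± 0.72 to 4.58 ± 0.034 (SD, n = 4). Its single stretch on chromosome 4 (141683851 to 141685599) lies wholly within exons of Ddi2 on the same strand, with 1749 bases shared, so its value is uncertain. The 20 genes of this and the preceding paragraph had no overlap between the groups, which the naming rule required.

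In all, 1581 genes passed the limma test at an adjusted p of 0.05, 13.3% of those tested. With SLIT2, 801 of them were higher and 780 lower. All 1581 had the same direction in replicates 1 and 2 as in replicates 3 and 4. The test itself favours such genes, since opposite effects in the sets would lower the mean difference and widen the residual spread. That agreement is therefore no separate evidence. With replicate number as a block, 3912 genes passed (1966 higher and 1946 lower), 33.0% of those tested, the 1581 among them. An absolute log2 difference of at least 0.5 held for 650 of the 1581 genes and of at least 1 for 163, of which 124 were higher. SLIT2 and vehicle values did not overlap at 2435 genes, 20.5% of those tested, where chance gives 2.86% for 8 exchangeable libraries. These libraries form replicate sets of close duplicates, so that share does not describe them, and none was computed for the sets. The count of genes past the limma test fell to 1021 without SLIT2 replicate 2 and to 688 with each duplicate averaged to 1 sample and the set as a block.

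**Figure D2:**
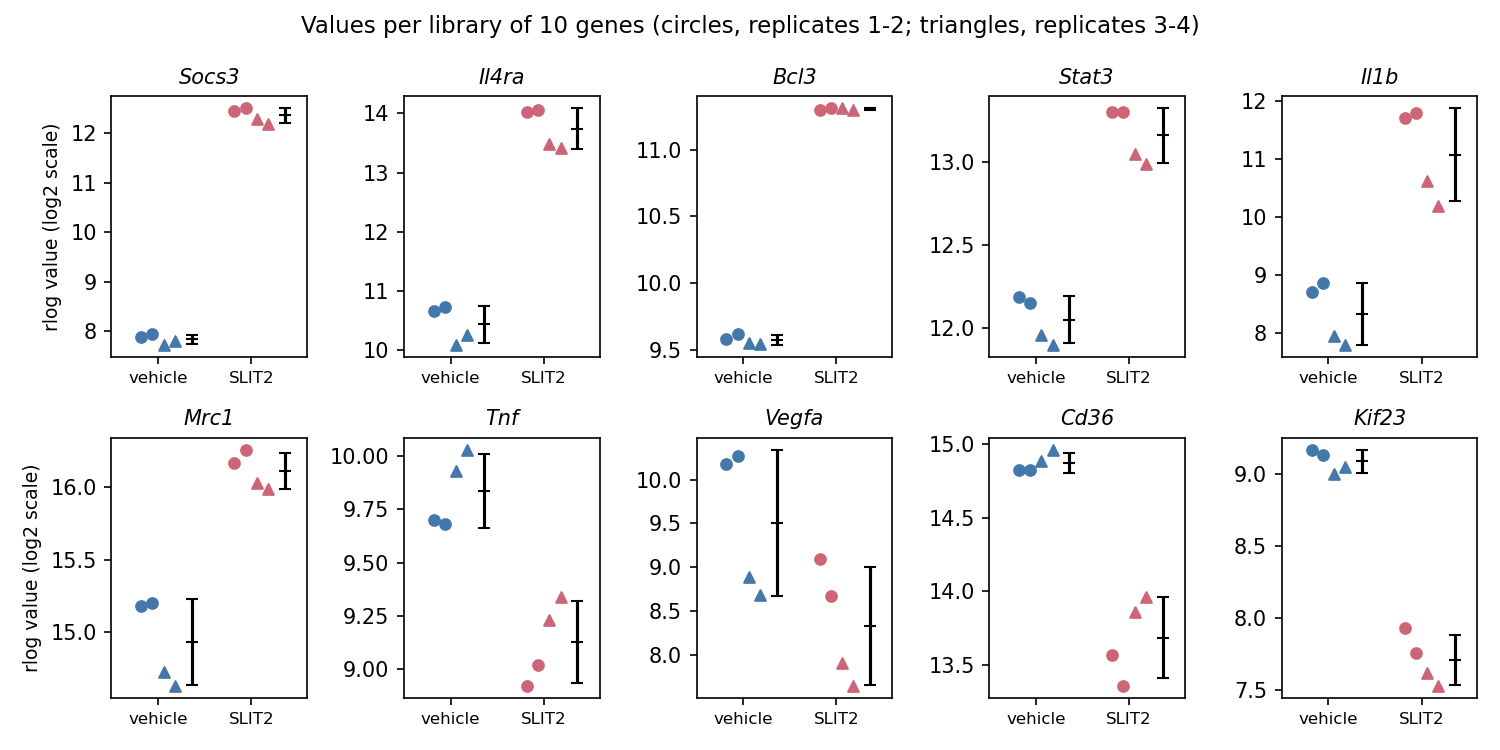
rlog values (vertical axes, log2 scale, each with its own range) of 10 genes in the vehicle (blue) and SLIT2 (red) libraries, with replicates 1 and 2 as circles, replicates 3 and 4 as triangles, and the mean with its SD in black. Socs3, Il4ra, Bcl3, Stat3, Il1b and Mrc1 lie higher with SLIT2 in every library, Tnf, Cd36 and Kif23 lie lower, and the Vegfa values overlap.

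Inflammatory genes moved in both directions. Among 29 tested genes of the list called NF-kB-driven, 10 rose and 3 fell (11 and 3 adjusted over the list alone, 17 and 5 with the replicate block). The list is not specific to NF-kB, since Socs3, its most raised member, is also counted below in the pattern linked to STAT3. Socs3, Saa3 and Il1b rose, while Tnf, the gene of tumour necrosis factor, fell by 0.71 (SE 0.12, adjusted p = 0.00570). The list was called higher by camera (adjusted p = 4.99e-04), and its call was lost with an estimated correlation (adjusted p = 0.615). Of 27 chemokine and chemotactic receptor genes, 6 rose and none fell (10 and 2 over the list alone; 14 and 4 with the block), Ccl7 by 2.04. That list had an adjusted p of 0.0173, and of 0.615 with an estimated correlation. In the inflammasome list, 5 of 18 genes rose and 3 fell, with Casp4 higher by 1.16 and Gsdmd by 0.34, and the list was not called (adjusted p = 0.439). Among 26 immediate early genes 6 rose and 9 fell, with a list adjusted p of 0.303. Ier3 rose by 1.90, Dusp4 fell by 1.26 and Egr2 fell by 1.06.

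Some antigen presentation and interferon-gamma-induced genes rose, while most members of these lists did not pass the limma test. Of 16 guanylate-binding protein, immunity-related GTPase and related genes, 7 rose and none fell (8 and 0 over the list alone). The gene the table calls Gbp5, whose identifier GENCODE M21 names Gbp2b, rose by 1.69, Gbp7 by 1.39 and Gbp3 by 1.34, and these paralogs may share reads. The list adjusted p was 2.88e-05, and 0.615 with an estimated correlation. In MHC class I presentation, 7 of 21 genes rose and none fell (13 and 1 with the block). Nlrc5, an activator of MHC class I genes, was higher by 0.99, Psmb10 by 0.54 and Tapbpl by 0.53 (list adjusted p = 2.59e-05, and 0.615 with an estimated correlation). In MHC class II presentation, 2 of 11 genes rose (6 over the list alone; 9 with the block), Ciita by 0.84 and H2-DMb1 by 0.39, with a list adjusted p of 0.00338 and of 0.615 with an estimated correlation.

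Type I interferon-stimulated genes differed between the replicate sets. None of 38 passed the limma test over all samples, 6 were higher and 0 lower at an unadjusted p under 0.05, and 7 were higher with the replicate block. Cxcl10 had the smallest p of the list, with a difference of 0.85 (adjusted p = 0.0734, 0.00391 with the block, 0.0225 without vehicle replicate 2 and 0.0574 with averaged duplicates). The median difference was 0.054 over all samples, -0.29 in replicates 1 and 2 and 0.41 in replicates 3 and 4. The list was called lower in replicates 1 and 2 alone (camera adjusted p = 0.00256) and higher in replicates 3 and 4 alone (adjusted p = 6.17e-10). Each of these fits rests on the spread within duplicates and was run at the preset correlation only. The difference between the sets itself was tested, and 37 of 38 members had the higher effect in replicates 3 and 4 (adjusted p = 6.25e-28, and 0.271 with an estimated correlation). Ifit1, named after its values were seen, differed by -0.63 in the first set and 0.69 in the second. Over all samples the list adjusted p was 0.400, and 0.964 with an estimated correlation. At the preset correlation it was 0.00408 without vehicle replicate 1 and 0.0445 without vehicle replicate 2, both higher.

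**Figure D3:**
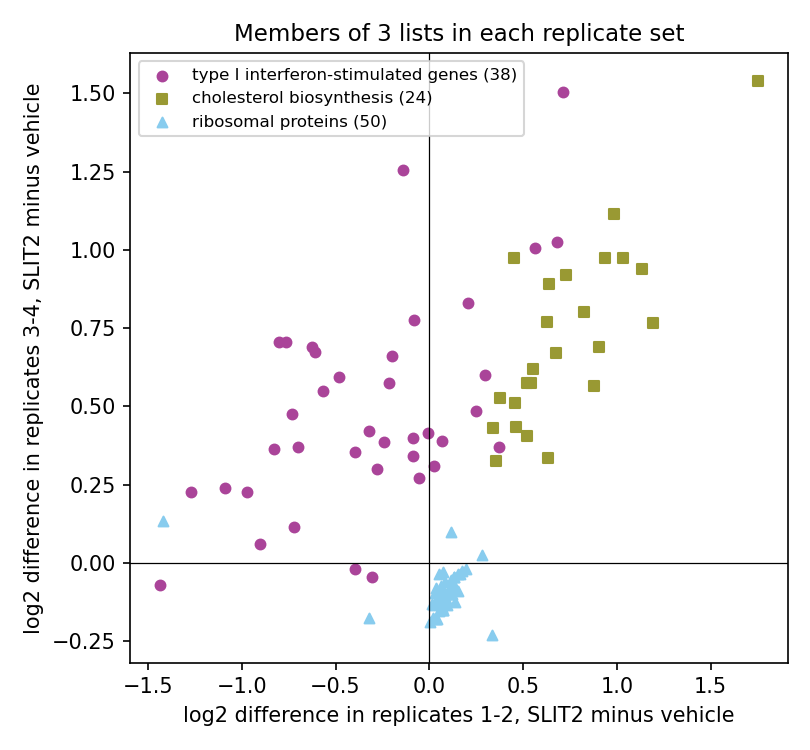
Log2 difference of SLIT2 minus vehicle in replicates 1 and 2 (horizontal axis) and in replicates 3 and 4 (vertical axis), with 1 point per gene for type I interferon-stimulated genes (circles, 38), cholesterol biosynthesis (squares, 24) and ribosomal proteins (triangles, 50). All 24 cholesterol genes lie above 0 on both axes, while 29 of the 38 interferon-stimulated genes lie below 0 in replicates 1 and 2 and 35 above 0 in replicates 3 and 4.

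Every tested gene of cholesterol biosynthesis rose. All 24 passed the limma test, with a median difference of 0.71 (0.64 in replicates 1 and 2 and 0.68 in replicates 3 and 4). Pmvk, a kinase of the mevalonate pathway (ENSMUSG00000027952, chromosome 3, 89454541 to 89469013), rose by 1.65 (SE 0.063, adjusted p = 7.71e-06). Fdps rose by 1.05 and Mvd by 1.04, both enzymes of the same pathway. Fdps shares 1124 exonic bases with Gm43738 on its strand. Camera gave an adjusted p of 1.42e-22, and of 0.183 with an estimated correlation, the smallest of any list. In the list of LXR targets and lipid handling, 5 of 27 genes rose and 7 fell (adjusted p = 0.744). Fasn and Scd2, enzymes of fatty acid synthesis and desaturation, rose by 1.11 and 1.07, and the lipid scavenger receptor gene Cd36 fell by 1.18 (SE 0.12, adjusted p = 6.56e-04).

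In the unfolded protein and integrated stress response, 14 of 29 genes rose and 2 fell (20 and 4 with the block). Nupr1 rose by 1.41 and Cebpb by 0.56, while Atf3 fell by 0.89 (list adjusted p = 3.68e-06, and 0.279 with an estimated correlation). In the NRF2 and oxidative stress list, 11 of 27 genes fell and 1 rose (19 and 2 with the block). Slc40a1, the iron exporter, fell by 1.11, Srxn1 by 0.93 and the catalase gene Cat by 0.76 (list adjusted p = 6.47e-07, and 0.573 with an estimated correlation). Glycolysis and hypoxia-response genes included 5 of 34 higher (10 and 4 lower with the block), Ndrg1 by 1.18, Ldha by 0.32 and Gapdh by 0.28. Their list adjusted p was 0.0326, 0.0552 with the replicate block and 0.740 with an estimated correlation. It was also lost without vehicle replicate 3 (adjusted p = 0.0814), SLIT2 replicate 1 (0.153) or SLIT2 replicate 2 (0.117), with a mean of at least 6 (0.0649), in replicates 3 and 4 alone (0.622), with averaged duplicates (0.0793) and by fry (0.148). For oxidative phosphorylation, 2 of 52 genes rose (20 with the block), Ndufs8 by 0.33 and Atp5o by 0.20, with a list adjusted p of 0.00158 and of 0.740 with an estimated correlation. The call was also lost with quantile normalization (adjusted p = 0.0507) and by fry (0.246).

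Of 54 cell cycle genes tested, 5 passed, 49 did not, and all 5 were lower (29 lower and 2 higher with the block), and 3 of 54 had a positive difference. Ccnd1, the gene of cyclin D1, fell by 1.24 (SE 0.099, adjusted p = 1.97e-04) and Stmn1, a microtubule regulator, by 0.74. The list adjusted p was 8.50e-06, 0.740 with an estimated correlation and 0.116 by fry. The median difference was -0.49 in replicates 1 and 2 and -0.20 in replicates 3 and 4.

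Macrophage surface and phagocytic genes changed in part. Mrc1, the mannose receptor gene (ENSMUSG00000026712), rose by 1.18 (SE 0.14, adjusted p = 0.00125). The Fc receptor genes Fcgr2b, Fcgr4 and Fcgr1 rose by 2.00, 1.87 and 1.17, while Cebpa fell by 0.66. The macrophage identity list had 4 of 19 genes higher and 2 lower (11 and 3 with the block), with an adjusted p of 0.0352 and of 0.615 with an estimated correlation. It was lost without vehicle replicate 3 (adjusted p = 0.0783), vehicle replicate 4 (0.0831), SLIT2 replicate 1 (0.0653) or SLIT2 replicate 2 (0.0576). Csf1r had a difference of -0.08 (adjusted p = 0.902) and Emr1, the older symbol of Adgre1, of 0.11 (adjusted p = 0.820). Arg1 stayed near the floor, at 0.42 in vehicle and 0.50 in SLIT2, and was not tested. In efferocytosis and phagocytic receptors, 7 of 26 genes rose and 6 fell (adjusted p = 0.439). In alternative activation, 4 of 23 rose and 6 fell (adjusted p = 0.632). In the lysosome list, 5 of 40 rose and 7 fell (adjusted p = 0.679), where Ctsc and Tfec rose by 1.51 and 1.32 and Lipa fell by 0.79.

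Of 24 SLIT-ROBO signalling genes, 3 fell and none rose, Nck2 and Evl by 0.57 each and Srgap3 by 0.54 (list adjusted p = 0.206). Of all genes tested 13.3% passed, and 12 of the 24 had a positive difference. Robo1 was listed at 0, and Robo2, Robo3 and Robo4 had values between -2.14 and -1.52. Slit2 itself was low, at 3.51 ± 0.49 in vehicle and 3.29 ± 0.17 in SLIT2 (SD, n = 4), and was not tested. A listed 0 does not show absence here, since Tyrobp, which macrophages express, was listed at 0 in every library. Among integrins and adhesion genes 1 of 25 rose and 7 fell (adjusted p = 0.0866), where Itgb3 fell by 1.15, Cd9 fell by 0.80 and Icam1 rose by 0.88. That list passed without vehicle replicate 3 (adjusted p = 0.0292), vehicle replicate 4 (0.0332), SLIT2 replicate 1 (0.0278) or SLIT2 replicate 2 (0.0391). With an estimated correlation over all samples, camera gave it an adjusted p of 0.740. Among angiogenic and growth factors and remodelling enzymes 6 of 25 rose and 5 fell (adjusted p = 0.995), Tgfbi rising by 1.92, Pgf by 1.37 and Pdgfc by 1.18. Vegfa had a difference of -1.18 (SE 0.46) with an adjusted p of 0.147, of 5.73e-04 with the replicate block and of 0.0362 with averaged duplicates and the set as a block.

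The osteoclast list was called lower, with 3 of 10 genes lower, Dcstamp, Itgb3 and Atp6v0d2 (adjusted p = 0.0464, and 0.615 with an estimated correlation). Its call was lost without vehicle replicate 1 (adjusted p = 0.103), vehicle replicate 2 (0.0868), SLIT2 replicate 3 (0.113) or SLIT2 replicate 4 (0.0727), and in replicates 3 and 4 alone (0.0733). Among monocyte genes 2 of 8 fell and none rose, Nr4a1 by 1.02 and Cd300e by 0.74, while the median was 0.23 and the list adjusted p 0.964. With the replicate block 4 monocyte genes were higher and 2 lower. Csf3r, from the neutrophil list, rose by 0.68, 1 of 5 tested (adjusted p = 0.303). Of stromal and endothelial genes 1 of 13 rose, Col3a1 by 0.67 (adjusted p = 0.211), passing at 0.0321 without vehicle replicate 4. Lists with fewer than 5 tested genes had no list test. Kmo rose by 1.91 among 3 dendritic cell genes and Cd4 fell by 0.60 among 4 lymphocyte genes. Kit, the only mast cell gene tested, differed by -0.51 (adjusted p = 0.0869, 0.0382 with the block and 0.170 with averaged duplicates). Ppbp, of 2 erythroid and megakaryocytic genes, differed by 1.15 (adjusted p = 0.0908, 0.0134 with the block, 0.0365 without SLIT2 replicate 4 and 0.133 with averaged duplicates).

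Yam1, named Gm42418 in GENCODE M21 and lying over an annotated ribosomal RNA gene on chromosome 17 (39846958 to 39848788), took between 1.94% and 4.99% of the summed linear rlog values in vehicle libraries and between 0.602% and 1.79% in SLIT2 libraries. Its difference was -1.68 (adjusted p = 0.0577, 1.73e-04 with the replicate block, 0.0338 with averaged duplicates and 0.0489 without SLIT2 replicate 1), and it was chosen after its values were seen. None of 50 ribosomal protein genes passed the limma test and 1 was lower at an unadjusted p under 0.05, with Rpl12 at -0.25 (adjusted p = 0.185, 0.0339 with the block and 0.124 with averaged duplicates) and a list adjusted p of 0.803. The list was called higher in replicates 1 and 2 alone (adjusted p = 1.91e-06) and lower in replicates 3 and 4 alone (adjusted p = 5.21e-06). The medians there were small, 0.078 and -0.098. Both fits rest on the spread within duplicates and were run at the preset correlation only. The difference between the sets had an adjusted p of 6.31e-22, and of 0.271 with an estimated correlation. None of 13 mitochondrially encoded genes passed the limma test and 1 was higher at an unadjusted p under 0.05, with mt-Nd4l at 0.18 (adjusted p = 0.0767, 0.0243 with the block and 0.191 with averaged duplicates) and a list adjusted p of 0.303.

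**Figure D4:**
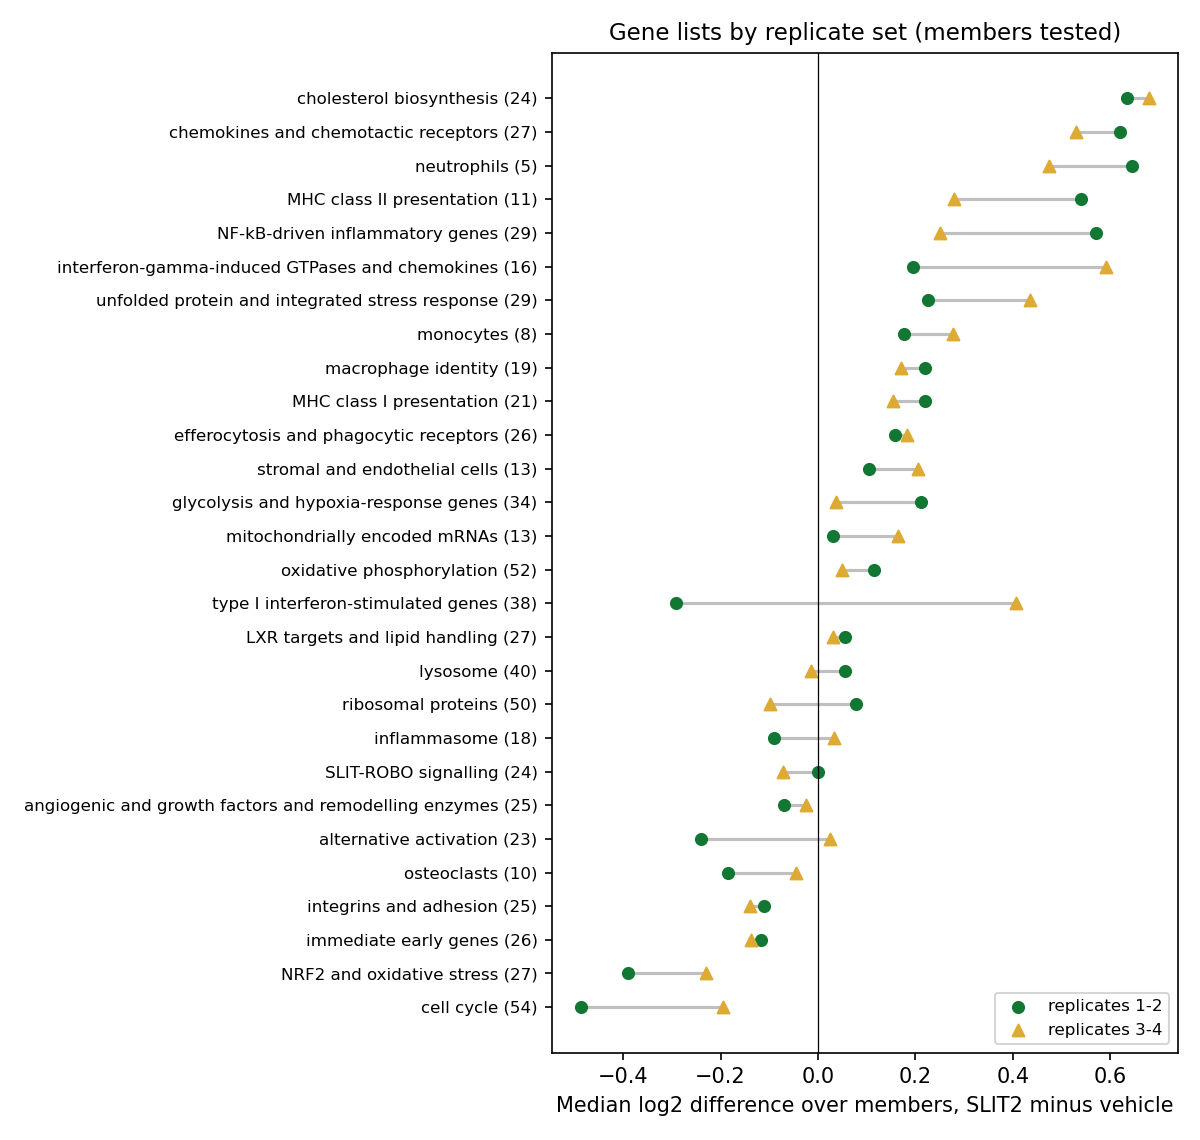
Median log2 difference of SLIT2 minus vehicle over the tested members of 28 gene lists (horizontal axis) in replicates 1 and 2 (circles) and in replicates 3 and 4 (triangles), with the number of members in brackets. Cholesterol biosynthesis lies at 0.64 and 0.68 and cell cycle at -0.49 and -0.20, and type I interferon-stimulated genes lie at -0.29 and 0.41.

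Of 29 lists tested, camera called 10 higher and 3 lower. Median differences in replicates 1 and 2 and in replicates 3 and 4 were 0.57 and 0.25 for NF-kB-driven genes, 0.20 and 0.59 for interferon-gamma-induced genes, 0.54 and 0.28 for MHC class II, 0.22 and 0.16 for MHC class I and 0.62 and 0.53 for chemokines. They were 0.21 and 0.038 for glycolysis, 0.12 and 0.050 for oxidative phosphorylation, 0.23 and 0.44 for the unfolded protein list and 0.22 and 0.17 for macrophage identity. For lists called lower they were -0.39 and -0.23 for NRF2 and -0.19 and -0.045 for osteoclasts. With an estimated correlation camera called none, and fry, which tests whether a list's genes move on balance 1 way, called 13, of which 10 were shared in the same direction. Those lost by fry were glycolysis, oxidative phosphorylation and cell cycle, and those gained were the inflammasome (adjusted p = 0.0256), efferocytosis (0.0448) and neutrophils (0.0190). For 12 of the 13 called lists the value with an estimated correlation was the highest over the alternatives run, and for cholesterol biosynthesis the highest was 0.243, with that correlation and the replicate set as a block. Adjusted over the list alone, the counts higher and lower were 16 and 3 for the unfolded protein list, 1 and 14 for NRF2, 7 and 2 for macrophage identity, 0 and 4 for cell cycle and 1 and 0 for oxidative phosphorylation. They were 5 and 7 for alternative activation, 6 and 8 for angiogenic factors, 6 and 9 for LXR targets, 9 and 7 for efferocytosis, 7 and 10 for immediate early genes, 3 and 2 for monocytes and 0 and 0 for stromal genes. In the lists not named in these 2 sentences nor given such counts elsewhere, they differed from the counts over all genes by at most 1. With the replicate block the SLIT-ROBO list had 10 genes lower and 0 higher, integrins 6 higher and 11 lower, angiogenic factors 10 and 10, LXR targets 10 and 11, efferocytosis 12 and 10, lysosome 10 and 8, alternative activation 9 and 10 and inflammasome 7 and 5. The mean and the median differed in sign for alternative activation (0.090 and -0.14), angiogenic factors (0.13 and -0.06) and the inflammasome (0.25 and -0.01). The test was directed lower for LXR targets and monocytes, whose medians were 0.09 and 0.23. Of 82 named genes past the test, 67 stayed past it in all 8 fits that left out 1 library. Ndufs8 lost its call in 8 of those fits (adjusted p up to 0.108), Atp6v0d2 (0.115), Col3a1 (0.107) and Fasn (0.0733) in 7, Cmah (0.0693) in 6, and Gapdh (0.0843), Icam1 (0.0777), Scd2 (0.0732) and Gbp7 (0.0824) in 5. H2-DMb1 (0.0645), Tox2 (0.0686), Rasgrp3 (0.0707), Ciita (0.0839), Cd9 (0.0680) and Kmo (0.0633) lost theirs in 4. With averaged duplicates and the set as a block, 23 of the 82 genes lost their call, at adjusted p between 0.0515 and 0.143. They were Ccl8, Steap4, Rsc1a1, Cmah, Evl, Srgap3, H2-DMb1, Psmb10, Tapbpl, Pgf, Gsdmd, Ldha, Gapdh, Ndufs8, Atp5o, Fasn, Lipa, Slc40a1, Srxn1, Cat, Nr4a1, Col3a1 and Pim1.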

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

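The splits of the samples, the tests on the replicate sets, on the interferon-stimulated genes and on the share of reads were chosen after the results they bear on had been seen; those of STAT3 target genes and of GC content were set before their values were looked at. The difference of effects between the replicate sets was also tested only after the sets had been seen.

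The first pattern is the division of replicates 1 and 2 from replicates 3 and 4. Xist lay 5.18 higher in replicates 3 and 4 on the log2 scale, and Ddx3y, Eif2s3y, Kdm5d and Uty lay lower by between 1.66 and 4.56, which is what cells from female animals in 1 set and male animals in the other would give. Sex may not account for the whole division. Of autosomal genes tested, 57.0% also differed between the sets, but that share cannot decide this, since sex may alter autosomal genes too. Separate culture, library or sequencing days cannot be told apart from sex because they would divide the samples the same way. The ratio of the SD between sets to that within duplicates had a median of 2.17, so repeat cultures or libraries of 1 pool of cells stay open for each duplicate.

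Between the SLIT2 and vehicle libraries, 1581 genes passed the limma test. Of the 35 splits of the 8 samples, 2 gave at least as many genes as the real split, so this count alone does not exclude chance; the other is the split by replicate set, with 4125 genes, and points to the structure of the samples. The highest count among the rest was 1, and with the replicate block the real split gave 3912 genes against a highest of 0 among the other splits that part the 4 pairs. Those other splits hold both treatments on each side, so the treatment difference adds to their residual spread and lowers their counts. With 8 splits that part the pairs, the real one included, this comparison does not exclude chance either.

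The second pattern is the rise of Socs3, Il4ra, Saa3 and Il1b, with Stat3 (1.11), Bcl3 (1.73) and Nfil3 (1.59), named after their values were seen, which are known targets of STAT3 signalling. A list of 9 further STAT3 targets was written before their values were looked at. Of these, 8 were tested, 5 rose and their median difference was 0.36 (camera p = 0.00105, and p = 0.0853 with an estimated correlation). That median passed the bound of 0.25 written for STAT3 activity but would be undecided with the 0.5 considered first. Fosl2 (0.76), 1 of the 5, was also in the immediate early list already tested. Without Fosl2 the middle value is that of Bcl6, 0.17, which is under the bound of 0.25. Endotoxin in the protein preparation, at a level that induces interferon-stimulated genes, was first tested over all samples, where their median was 0.054; the test was split by set only after the sets were seen to go opposite ways, since a pooled median then decides nothing. In replicates 1 and 2 the median was -0.29, with 29 of 38 members below 0, which argues against such endotoxin only for these genes at 16 hours. Cxcl10 of the same list rose there by 0.68, and interferon-gamma-induced genes had a median of 0.20. NF-kB-driven genes had a median of 0.57 in that set, with 6 of 29 below 0, Tnf (-0.72) among them. Il6, Il12b and Nos2 of that list were not tested. The values rest on the duplicates of 1 set, so endotoxin is not excluded there. In replicates 3 and 4 the median of the type I interferon-stimulated genes was 0.41, which leaves it open. Lower levels of endotoxin, or another component of the preparation, cannot be told apart from SLIT2, because the design has 0 arms with an inactivated or blocked protein.

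The third pattern is the rise of all 24 cholesterol biosynthesis genes. After removal of a smooth trend on GC content and transcript length, in the fit with the replicate block, their median was 0.73 against 0.71 before, and all 24 stayed above 0, which argues against that trend. The list's median lay 0.70 above that of all genes tested, against an SD over its members of 0.29. A change in the share of reads taken by 1 transcript such as Yam1 would move all genes alike, so it would not set 1 list apart. Both medians were known when the bound was written, so the comparison had a fixed outcome and was no test. It replaced a test on the median over all genes alone (0.0025), which the scaling to library size sets near 0. A change in cell density or in serum lipid may also raise these genes and was not tested.

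The effect of SLIT2 differed between the replicate sets at 521 genes, 130 of them among the 1581. Of the 91 named genes tested it differed at 18, given here as the effect in replicates 3 and 4 minus that in 1 and 2. It was smaller in replicates 3 and 4 for Steap4 (-2.06), Ccl8 (-1.81), Ppbp (-1.06), Ccl12 (-0.87), Pgf (-0.68), Gja1 (-0.46), Pim1 (-0.42) and Icam1 (-0.34). The rise was larger there for Tgfbi (0.63), Gbp7 (0.55), Fcgr1 (0.46) and Mrc1 (0.31). The fall was smaller there for Rsc1a1 (1.13), Nr4a1 (0.93), Slc40a1 (0.61), Lipa (0.46), Srxn1 (0.40) and Cat (0.37).

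The difference between the sets passed the camera test for 12 lists and for 0 with an estimated correlation (smallest adjusted p = 0.271), and these tests rest on the spread within duplicates. The median of the members' differences was 0.79 for type I interferon-stimulated genes (adjusted p = 6.25e-28), -0.20 for ribosomal proteins (6.31e-22) and 0.18 for alternative activation (0.0107), whose medians had opposite signs in the sets. By fry their adjusted p was 0.0287, 0.0214 and 0.0214, and of the 12 lists oxidative phosphorylation (0.126) and mitochondrially encoded mRNAs (0.127) did not pass. The median difference was 0.31 for interferon-gamma-induced genes, 0.24 for cell cycle, 0.15 for mitochondrially encoded mRNAs, 0.13 for the unfolded protein list and 0.11 for NRF2. It was -0.31 for MHC class II, -0.17 for glycolysis and hypoxia-response genes, -0.15 for NF-kB-driven genes and -0.068 for oxidative phosphorylation.

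In 5 of 182 groups of 4 libraries a single library lay far from the rest for the range of its group. The rule set the gap to the nearest library against that range, so a small distance can pass it. Chance gives about 1 in 20 for exchangeable libraries, which close duplicates are not, so the count is not set against it. Among SLIT2 libraries the cases were Rsc1a1 at 4.63 (the others at 4.56 to 4.57) and Srxn1 at 11.69 (the others at 11.6 to 11.61). Among vehicle libraries they were Nlrc5 at 9.25, Tapbpl at 9.39 and Fasn at 8.18.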

How the results depend on the processing

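Alternatives on the replicate sets and on averaged duplicates were added after the data were seen. Those for a pseudocount and for a count tool were not run, because the values are on a log2 scale. The main test called 1581 genes (801 higher, 780 lower), 13 lists, and treatment took 37.3% of the sum of squares. All 1581 genes kept their direction in every alternative, except that a mean of at least 6 tested 1481 of them. The alternatives use the same libraries or part of them, so this agreement is partly built in. The replicate block, with the pairing of same-numbered samples, gave 3912 genes (1966 and 1946) and 12 lists, glycolysis being lost, and otherwise changed no list's call; 7 named genes short of the threshold in the main test passed with it, of which Vegfa and Yam1 also passed with averaged duplicates and the set as a block. An absolute difference of at least 0.5 gave 650 (336 and 314) and a test against a fold of 1.2 gave 354 (208 and 146), both stricter by construction. The block on the replicate set gave 4652 (2365 and 2287), replicates 1 and 2 alone 3962 (2004 and 1958), replicates 3 and 4 alone 2889 (1474 and 1415), and averaged duplicates with the set as a block 688 (373 and 315), with 557 of the 1581 shared. The fits within 1 set rest on the spread within duplicates, and their list tests were run at the preset correlation only. Leaving out each library gave 1021 to 1254 genes (517 to 665 higher, 504 to 602 lower). It gave 12 to 14 lists and a treatment share of 35.4% to 38.3%. The share was 39.6% with a mean of at least 6. Filters, variance priors, scaling and weights gave 1218 to 1598 genes and 12 or 13 lists. With an estimated correlation, with or without the block on the replicate set, 0 lists were called; the smallest adjusted p without the block was 0.183.

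Leaving out 1 library makes the sets unequal in 1 group, so without a block part of the set difference enters the treatment difference. Csf1r, with a difference of -0.75 for replicates 3 and 4 minus 1 and 2, moved from -0.08 to 0.045 without vehicle replicate 1. Lists that changed direction were mostly far from the threshold, and apart from that imbalance the cause was not tested. Monocytes did so with the replicate block (adjusted p = 0.651), a mean of at least 6 (0.940), quantile normalization (0.954), the block on the replicate set (0.663, and 0.822 with an estimated correlation), replicates 1 and 2 alone (0.536), replicates 3 and 4 alone (0.768) and averaged duplicates (0.755). Neutrophils did without a filter (0.805), and LXR targets with averaged duplicates (0.855). In replicates 1 and 2 alone, interferon-stimulated genes (0.00256), ribosomal proteins (1.91e-06) and mitochondrially encoded mRNAs (0.739) turned; in replicates 3 and 4 alone, alternative activation (0.884) and lysosome (0.848) did. Leaving out 1 library turned interferon-stimulated genes (vehicle 3 or 4), ribosomal proteins (vehicle 3 or 4), angiogenic factors (vehicle 3 or 4, SLIT2 1 or 2), monocytes (vehicle 2, SLIT2 3 or 4), Csf1r (vehicle 1 or 2, SLIT2 3 or 4) and Emr1 (vehicle 3 or 4). Over the 8 fits their adjusted p ran from 0.00408 to 0.969, 0.0979 to 0.998, 0.677 to 0.934 and 0.775 to 0.978, the difference of Csf1r from -0.22 to 0.058 and that of Emr1 from -0.0050 to 0.23. With averaged duplicates 23 of the 82 named genes past the threshold lost their call, 3 did without a filter, in replicates 3 and 4 alone 3, with quantile normalization 2, with median centring 2, and 1 each without a trend, with a robust prior and in replicates 1 and 2 alone. Leaving out 1 library lost 3 to 15, and a mean of at least 6, array weights and either block lost 0. Mitochondrially encoded mRNAs passed in replicates 3 and 4 alone (0.0438). Without read counts, the limit that depth sets on these calls is unknown.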

Other observations

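Pim1 and Sbno2, both known STAT3 targets, were chosen after their values were seen. Pim1, a kinase gene, rose by 0.76 (SE 0.085, adjusted p = 8.80e-04). Sbno2 was near the floor of the table in every library, at -1.70 in the SLIT2 group, and was not tested. Among the STAT3 targets listed before their values were looked at, Cebpd rose by 0.94, Batf by 0.82, Fosl2 by 0.76, Tnfrsf1a by 0.55 and Bcl6 by 0.17. Mcl1 had a difference of 0.085 (adjusted p = 0.317), Prdm1 of -0.01 (adjusted p = 0.906) and Il6st of -0.08 (adjusted p = 0.764). Fosl2 is also in the list of immediate early genes.

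Effects in replicates 1 and 2 correlated with those in replicates 3 and 4 at a Pearson r of 0.759 across the 11851 genes tested, which are not independent replicates. Socs3 rose by 4.57 in the first set and 4.47 in the second, Il4ra by 3.35 and 3.28 and Bcl3 by 1.71 and 1.76.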
